A study of Mus musculus with 3 samples.

How the data were processed

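RNA from 3 sorted populations of mouse spleen dendritic cells (DCs) was measured on Affymetrix Mouse Gene 1.0 ST arrays, which read whole transcripts with many short probes per probe set. Each of the 3 groups has 1 array: Esam(hi) cells of control mice, Esam(lo) cells of control mice, and Esam(lo) cells of mice in which CD11c-Cre deletes the floxed Rbpj gene. Per the labels, each array holds RNA from the combined spleens of 2 to 3 mice. Lymphoid and erythroid cells were first removed on magnetic columns, and CD11c(hi) CD11b+ cells were then sorted by flow cytometry. The control mice were littermates without Cre, and every mouse carried a GFP reporter in the Cx3cr1 gene. RNA was extracted on silica columns, amplified with a whole-transcript kit and labelled with biotin, per the labels' protocols.

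The deposited values are log2 expression values, 1 per probe set and array. Per the submitters' processing notes they were made with RMA and Affymetrix Expression Console; the versions are not given in the sources used here. RMA subtracts background, equalises the arrays' distributions and condenses the probes of a probe set by median polish. Which arrays were normalized together is not stated. The 3 columns do not share 1 distribution, because their quartiles differ, so differences in scale between arrays remain in the values. Median polish over few arrays also gives many probe sets exactly equal values on several arrays. At least 1 exact tie was found in 57.1% of genes, and an exact tie therefore does not show that a gene did not differ.

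The table has 35556 probe sets and no missing values. Gene names came from a table of the platform's annotation, which names 21789 probe sets with 1 gene, 1621 with several and 12146 with none. Only probe sets with 1 gene were used. Their Entrez numbers were looked up in a gene table of assembly GRCm38.p6, used for names and gene types only: 21698 were found, 91 were not, and no symbol changed. The genome build behind the array annotation is not given in the sources used here, so no coordinates are reported. A gene with several probe sets (999 of 19938 genes) was represented by the one with the highest mean over the 3 arrays.

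With 1 array per group there is no replicate error, so no test, p-value, standard error or standard deviation between replicates was computed, and the number of arrays limits the precision of every value. Standard deviations given below are over genes. Genes were counted by a rule of size fixed before the data were examined: at least 2-fold apart on the deposited values, with the brighter array above background. Background was the 95th percentile of 1194 olfactory and vomeronasal receptor genes on the same array, as these genes are silent in most tissues other than the nose. It lay at 7.17 on the control Esam(hi) array, 6.76 on the control Esam(lo) array and 6.87 on the array labelled RBPJ-deficient. Where the dimmer array was not above background, the fold is given as a lower bound ("at least"), computed against that array's background level. The 95% intervals on shares of genes are Wilson intervals over genes, which are not independent, and cover neither animal nor array variation.

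Named genes were chosen by a rule fixed before the data were examined. It takes the 12 genes farthest apart in each direction, without provisional symbols, small RNAs or immunoglobulin and T cell receptor segments. It adds the sort markers, Rbpj, Notch2 and up to 4 members of each gene list. The 30 gene lists were written before the data were examined, from general knowledge of the field. That knowledge includes this study, so the Notch, CD11b+ DC and monocyte lists are not independent evidence of a direction. Of 568 entries, 514 were on the array. The sort markers were left out of the list summaries, which leaves 29 lists. Members above background on at least 1 array entered a list's median, which was ranked among 10000 random lists of the same size matched in 20 bins of mean level. The resulting percentile describes these arrays and is not a p-value; the lowest that 10000 draws can give is 0.01 and the highest 99.99. Of the 87 percentiles computed, 38 lay outside 2.5 to 97.5, where 4.35 would for lists drawn at random. The 87 are not independent, because lists share genes and the comparisons share arrays. Members of a list may also vary together, so these counts do not measure chance.

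The position of the array labelled RBPJ-deficient between the controls was computed per gene, with 0 at the control Esam(lo) value and 1 at the control Esam(hi) value. Comparisons that share an array were set beside 100 draws of simulated unchanged arrays, all with noise taken from the difference between the 2 Esam(lo) arrays. Alternatives fixed beforehand were no filter on dim genes, a stricter filter at each array's 75th percentile, centring each array on its median, quantile normalization, and removal of the trend of the difference on mean level. Thresholds of 1.5-fold and 3-fold, the mean of a gene's probe sets, all list members and list means were also fixed beforehand. The trend was a lowess curve with span 0.3 and 3 iterations; only this span was run, and removing it can also remove real differences that go with level. Alternatives chosen after seeing the data were protein-coding genes without chemosensory receptors, this set with the trend removed, genes with 3 distinct values, and dim values raised to background.

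The counting steps were tested on simulated data for the comparison of the control arrays over 19938 genes. All of the genes made 3-, 4- or 6-fold different were called, 2% of those made 1.5-fold different, and 0% of the unchanged genes. The simulated noise came from the difference between the 2 Esam(lo) arrays, whose SD over genes was 0.15, against 0.57 between the controls. These shares therefore check the counting steps and give no error rate for the genes counted between the controls. Of 200 unchanged simulated lists, 7% fell outside percentiles 2.5 to 97.5, against 5% intended. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The probe sets with several names or none were left out of the comparisons; those with none appear once in the closing section.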

Results

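The study asks how Notch2 and its nuclear partner RBPJ shape CD11b+ dendritic cells of the mouse spleen. DCs take up antigen and present it to T cells, and Esam is an adhesion molecule that divides the CD11b+ DCs of the spleen into subsets. CD11c(hi) CD11b+ cells of control mice were sorted as Esam(hi) cells with little Cx3cr1-GFP reporter and as Esam(lo) cells with much of it. Cells of mice with Rbpj deleted in CD11c-expressing cells were uniformly Esam(lo) and GFP(hi), per the labels. Each group was measured once, on 1 array of RNA from 2 to 3 mice, so there are no replicates and every difference below compares arrays. Median log2 values over all probe sets were 6.67 on the control Esam(hi) array, 6.55 on the control Esam(lo) array and 6.56 on the array labelled RBPJ-deficient. Of 19938 genes, 8175 (41.0%), 9537 (47.8%) and 9108 (45.7%) were above background on these arrays.

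The targeted gene and the sort markers were read first. Rbpj (probe set 10521913) had log2 values of 9.85, 9.85 and 10.04 on the control Esam(hi), control Esam(lo) and RBPJ-labelled arrays, so it was not lower on the array labelled RBPJ-deficient. Its other probe set (10521911) was below background on all 3 arrays, at 6.11, 5.63 and 5.63. How many of these probes lie in the deleted exons is not known here, and the gene table lists 3 pseudogenes of Rbpj, so these values do not check the label. The array is therefore called "labelled RBPJ-deficient" throughout, and directions drawn from it rest on that label. Esam (10584317), which defined the sort, was at least 2.04-fold higher on the control Esam(hi) array (7.79) than on the control Esam(lo) array (6.57, below background), and it read 6.12 on the labelled array, also below background. Cx3cr1 (10597743), which carries the reporter, was 2.40-fold higher on the control Esam(lo) array, with values of 8.32, 9.58 and 9.58. With the level trend removed its difference, control Esam(hi) minus control Esam(lo), was -0.84, short of 2-fold. Itgam, the gene for CD11b, read 9.50, 10.57 and 10.79, and Itgax, the gene for CD11c, read 12.36, 12.50 and 12.44. The small control difference of Itgax (-0.13) turned positive (0.20) with the level trend removed. Notch2 (10494595) was well above background on all 3 arrays, at 10.87, 11.40 and 11.50.

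The first comparison asks what distinguishes Esam(hi) from Esam(lo) CD11b+ DCs in control mice. Monocyte genes were lower on the Esam(hi) array: all 30 members above background had lower values there, 24 of them at least 2-fold. Lyz2, the macrophage form of lysozyme, read 9.97 on the Esam(hi) array and 13.06 on the Esam(lo) array, an 8.53-fold difference. Csf1r, the receptor for the main macrophage growth factor, read 8.62 and 11.67; it is named after its values were seen. Ccr2, which draws monocytes out of bone marrow, was at least 5.55-fold lower (6.32 and 9.64), and Fn1, encoding fibronectin, was 11.3-fold lower (7.62 and 11.12). Dtx1, a direct target of Notch signalling, was 3.25-fold higher on the Esam(hi) array (11.25 and 9.55).

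By the 2-fold rule, 75 genes were higher and 1066 lower on the Esam(hi) array than on the Esam(lo) array, out of 9196 above background. The lower genes were thus 93.4% of 1141 (95% Wilson interval 91.8 to 94.7). Many differences went with level: genes at levels of 9 to 10 had a median difference of -0.51, and those at 6 to 7 had 0.15. With that trend removed, 180 genes were higher and 487 lower (73.0% lower, interval 69.5 to 76.2), and with quantile normalization 150 were higher and 651 lower (81.3%). Of the 1066 lower genes, 464 remained 2-fold lower with the trend removed, and 71 of the 75 higher genes remained.

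**Figure D1:**
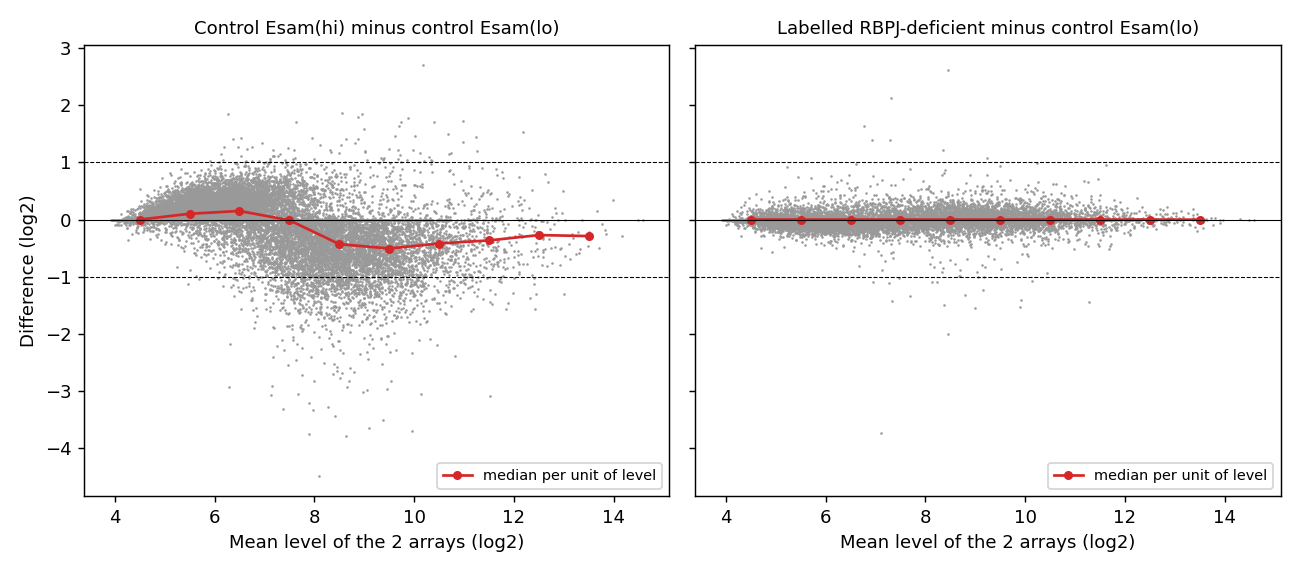
Log2 difference of each gene (vertical axis) against the mean log2 level of the pair of arrays (horizontal axis), for control Esam(hi) minus control Esam(lo) on the left and the array labelled RBPJ-deficient minus control Esam(lo) on the right. Grey points are genes, red points joined by lines are medians per unit of level, and dashed lines mark 2-fold; the left medians fall from 0.15 at levels 6 to 7 to -0.51 at 9 to 10, and the right medians lie at 0 or within 0.01 of it.

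The 12 named genes farthest below on the Esam(hi) array included several myeloid surface receptors. Adgre4, an adhesion receptor of the F4/80 family, was at least 10.3-fold lower, with log2 values of 6.74 on the Esam(hi) and 10.53 on the Esam(lo) array. The C-type lectin genes Clec12a (at least 6.07-fold), Clec4a3 (at least 7.78-fold) and Clec4e (at least 3.63-fold) were lower too. Serpinb10, a serine protease inhibitor, was at least 9-fold lower (5.86, below background, and 10.34). Wfdc17 was 12.97-fold lower and Ace, the angiotensin-converting enzyme, 12.5-fold lower. Hpgd, which breaks down prostaglandins, was at least 6.65-fold lower and the transporter gene Abca9 at least 5-fold lower; Fn1, Ccr2 and Lyz2 complete the 12.

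Higher on the Esam(hi) array were Gpr4, a proton-sensing receptor (9.49 and 7.63, 3.63-fold), and Arap2 (9.88 and 8.03, 3.60-fold). Tnf, the cytokine, was 2.75-fold higher (10.74 and 9.29), Adam23 2.72-fold, Slco5a1 3.27-fold and Dtx1 3.25-fold. Ifnz (3.46-fold), Krtap5-3 (2.76-fold) and Srsy (3.44-fold) belong to families of similar genes whose probes can share signal; Srsy, a Y-linked multicopy gene, has 19 probe sets here. The other 3 of the 12 were the olfactory receptor genes Olfr1331, Olfr316 and Olfr320, whose Esam(hi) values of 7.18, 7.24 and 7.62 lay near the background level. Of the 75 higher genes, 26 were not protein-coding and 6 were chemosensory receptors.

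**Figure D2:**
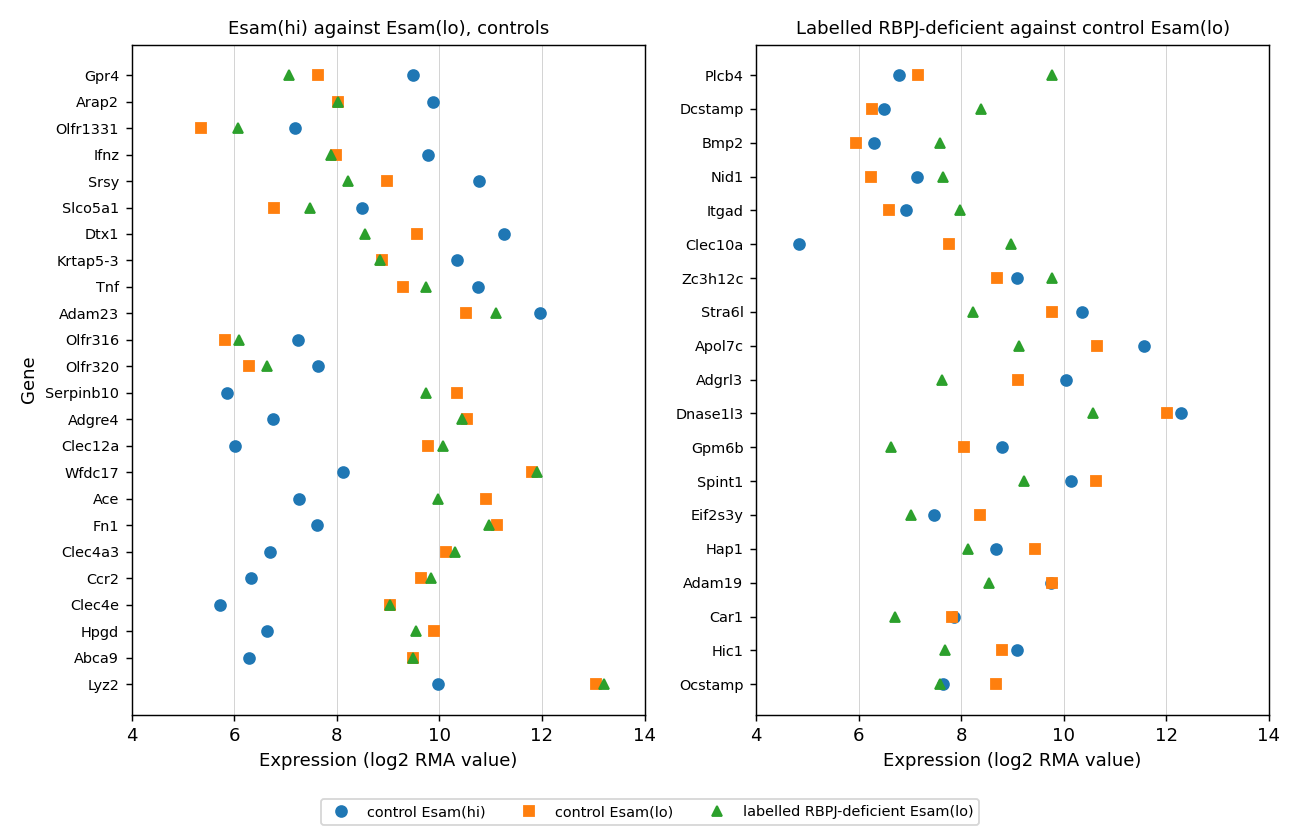
Log2 expression values (horizontal axis) of named genes (vertical axis) on the control Esam(hi) array (circles), the control Esam(lo) array (squares) and the array labelled RBPJ-deficient (triangles), 1 array each, with genes chosen from the control comparison on the left and from the comparison of the Esam(lo) arrays on the right. For Lyz2 the circle lies at 9.97 and the square and triangle at 13.06 and 13.20; for Plcb4 only the triangle lies high, at 9.76.

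Of the 9 gene lists below the central 95% of random lists of like level, 3 were lists of monocytes or macrophages, and the others ranged from lectin receptors and lysosomes to the cell cycle, neutrophils and natural killer cells. The monocyte list had a median difference of -1.56, against -0.42 for random lists (percentile 0.01), and -1.20 with the trend removed (0.01, with 20 members 2-fold lower). Of 20 Fc and C-type lectin receptor genes, 14 were at least 2-fold lower and none higher (median -1.60, percentile 0.01); 4 of the list's genes are also in the monocyte list. Fcgr4, the receptor for IgG2 immune complexes, read 5.70 on the Esam(hi) and 8.60 on the Esam(lo) array and is also named after its values were seen. Among macrophage core genes 6 of 14 were lower (median -0.93, percentile 0.06), including Cd68 (2.42-fold) and Tlr8 (at least 2.83-fold); with the trend removed 2 remained 2-fold lower (median -0.63), without Cd68. For red pulp and marginal zone macrophages 4 of 9 were lower (median -0.79, percentile 1.27), including Hpgd and C1qb (3.12-fold).

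Genes of lysosomes and lipid handling were lower as well, 9 of 17 at least 2-fold (median -1.14, percentile 0.01), among them the cathepsin gene Ctsb at 9.34 on the Esam(hi) and 11.13 on the Esam(lo) array. In the complement and coagulation list 5 of 11 were lower (median -0.92, percentile 0.10), led by Thbs1 (8.12 and 10.94) and F13a1 (at least 3.29-fold). Of 24 cell cycle genes 22 had lower values and 4 were 2-fold lower (median -0.79, percentile 0.02), such as Mcm7 (2.22-fold) and Top2a (2.07-fold). With the trend removed the cell cycle median was -0.43 and 1 gene remained 2-fold lower, neither Mcm7 nor Top2a. Neutrophil markers moved the same way: 7 of 15 were at least 2-fold lower on the Esam(hi) array (median -0.94, percentile 0.03), with S100a8 at 8.35 and 10.53 and Lcn2 at 10.80 and 12.25. With the trend removed 4 neutrophil markers, 7 lysosome genes, 6 complement genes and 1 natural killer marker were 2-fold lower. Both natural killer markers above background were lower, Klrk1 at least 2.97-fold and Klrd1 2.19-fold (median -1.65, percentile 0.46).

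Notch target genes lay on the other side. Only 4 of the 9 were above background, with a median difference of 0.46 against -0.33 for random lists (percentile 99.83). Dtx1 was the only one at least 2-fold higher; Hes5 differed by 0.55, Notch3 by 0.36 and Hes1 by -0.79. The B cell list also stood high (median 0.34, percentile 99.22), from 4 members that did not all differ the same way: Blk was at least 1.77-fold higher, and Cd79b read 8.20 on the Esam(hi) and 9.12 on the Esam(lo) array. The classical DC core list had a median near 0 (-0.09) where random lists of its level had -0.44 (percentile 99.71), and the median turned positive with the trend removed (0.29) and with quantile normalization (0.17). None of its 26 members was 2-fold apart on the deposited values, and Ccr7 and H2-Eb2 were 2-fold higher with the trend removed; Ccr7, which guides DCs to T cell zones, read 12.48 on the Esam(hi) and 11.73 on the Esam(lo) array.

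Other groups lay within the central 95% of random lists on the deposited values. The medians were -0.25 for CD11b+ CD4+ DC genes, -0.17 for MHC class II and antigen presentation, -0.17 for Notch pathway components, -0.40 for DC transcription factors, -0.13 for lymphotoxin and NF-kB genes, and -0.16 for immediate early genes. Each of these 6 turned positive with the trend removed, at 0.05, 0.09, 0.02, 0.02, 0.27 and 0.22 respectively, and the lymphotoxin and NF-kB list then lay at percentile 98.0, above the central 95%. Within them, the lectin gene Cd209a was 5.23-fold lower on the Esam(hi) array, Irf8 3.27-fold, Zeb2 2.95-fold and the gamma-secretase subunit gene Psenen 2.61-fold. Medians were -0.48 for pattern recognition receptors, with 8 of 20 lower (percentile 14.7, and 0.79 with the trend removed), -0.64 for cytokines and chemokines, with 9 of 22 lower and Tnf higher, and -0.44 for chemokine receptors, with 5 of 15 lower. With the trend removed, 6 cytokine and chemokine genes were 2-fold lower and 1 higher, and 2 chemokine receptor genes were lower and 1 higher. The interferon-stimulated list had -0.51, with 3 of 19 lower including Cxcl10 (4.07-fold), and the housekeeping list -0.79 (-0.41 with the trend removed). All 11 housekeeping genes had lower values on the Esam(hi) array, 3 of them by at least 2-fold (1 with the trend removed), with Hprt 3.39-fold lower. All 11 were also higher on the labelled array than on the Esam(hi) array.

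Markers of other cell types within that range were those of CD8+ DCs (median -0.14), plasmacytoid DCs (-0.01), T cells (0.02), erythroid cells (0.04) and platelets (0.62), and the sex-linked genes had -0.35. The sign of the plasmacytoid, T cell and erythroid medians was not stable across scalings. Among CD8+ DC markers Clec9a was at least 4.10-fold lower on the Esam(hi) array and Naaa 5.03-fold lower. Of the 9 above background 6 were lower and 3 higher, with Ly75 at 8.20 on the Esam(hi) and 7.32 on the Esam(lo) array. With the trend removed 4 were 2-fold lower and 2 higher. Over 29 lists, 9 lay below and 3 above the central 95% of random lists.

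**Figure D3:**
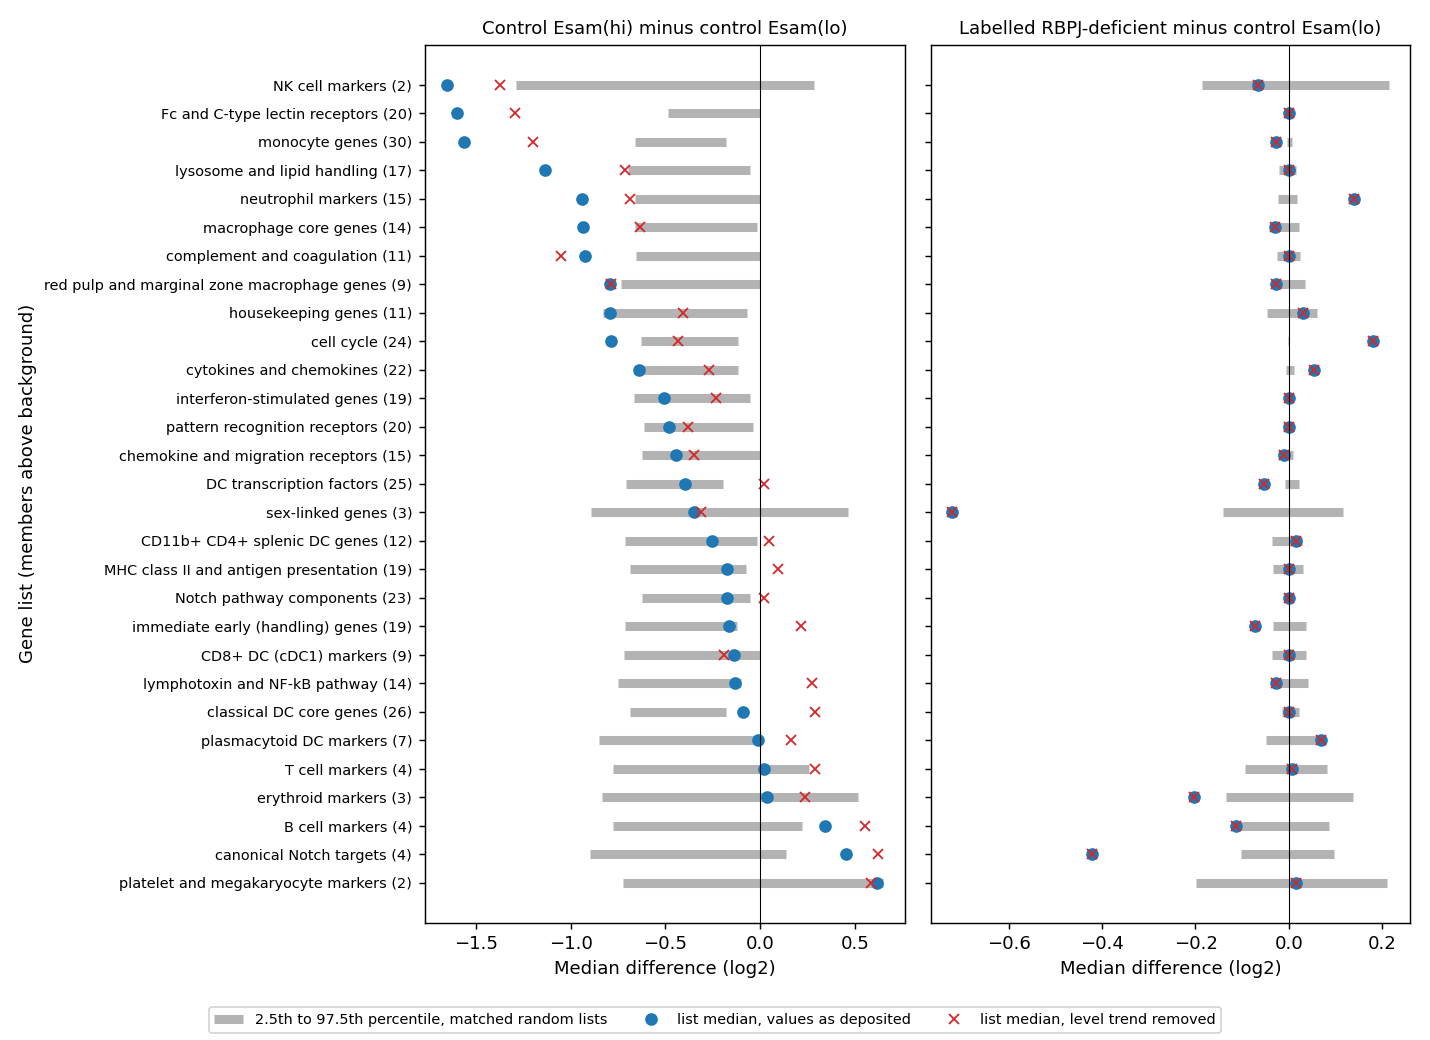
Median log2 difference of each gene list (horizontal axis; lists on the vertical axis with their number of members above background) for control Esam(hi) minus control Esam(lo) on the left and the array labelled RBPJ-deficient minus control Esam(lo) on the right, which have different scales. Blue circles are deposited values, red crosses have the level trend removed, and grey bars span the central 95% of 10000 random lists matched on level for the deposited values; monocyte genes lie at -1.56 on the left and -0.03 on the right.

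The second comparison sets the array labelled RBPJ-deficient against control cells of the same Esam(lo) phenotype. Of 9348 genes above background, 7 were at least 2-fold higher and 18 lower. Plcb4, a phospholipase C, was 6.11-fold higher on the labelled array (9.76 against 7.15). Dcstamp, which cells need to fuse into osteoclasts and giant cells, was at least 3.06-fold higher (8.38 against 6.26), while the related gene Ocstamp was 2.12-fold lower (7.59 against 8.67). The lectin gene Clec10a was 2.31-fold higher, Zc3h12c 2.10-fold, the integrin gene Itgad at least 2.33-fold, the basement membrane gene Nid1 at least 1.84-fold and Bmp2, a growth factor, at least 1.77-fold.

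Lower on the labelled array were Stra6l (2.93-fold), Apol7c (2.87-fold), the adhesion receptor gene Adgrl3 (2.80-fold) and Dnase1l3 (2.73-fold), a secreted nuclease that myeloid cells make, which read 10.56 against 12.01. Gpm6b was at least 2.27-fold lower, Spint1 2.64-fold, Hap1 2.49-fold, Adam19 2.34-fold, Hic1 2.14-fold and Car1 at least 1.94-fold. Eif2s3y, on the Y chromosome, was 2.53-fold lower. The share of lower genes, 72.0% of 25, had a Wilson interval of 52.4 to 85.7.

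All 4 Notch targets above background had lower values on the labelled array than on the control Esam(lo) array, none by 2-fold. Dtx1 fell just short of the rule, at 8.56 against 9.55 (difference -0.997), and Hes1 read 7.91 against 8.66 (-0.75); Notch3 and Hes5 differed by -0.09 and -0.04. The list's median was -0.42 where random lists gave 0 (percentile 0.01). None of the 30 monocyte genes was 2-fold apart: 10 were higher, 18 lower and 2 tied (median -0.03, percentile 0.11), with Lyz1 differing by 0.98 and Ace by -0.93. Cell cycle genes had slightly higher values, 17 higher and 3 lower of 24, with a median of 0.18 (percentile 99.99) and none 2-fold apart. Neutrophil markers did likewise (median 0.14, percentile 99.99). The sex-linked list had a median of -0.72 (percentile 0.01) from 3 members above background, which is the value of Kdm5d alone. Kdm5d read 6.82 on the labelled array, below background, against 7.55. Xist went the other way, at 12.09 against 11.13, and Eif2s3y was lower, at 7.02 against 8.36.

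Over all lists, 8 lay below and 3 above the central 95% of random lists. The others outside were cytokines and chemokines (0.06), DC transcription factors (-0.05), immediate early genes (-0.07), macrophage core genes (-0.03), B cell markers (-0.11) and erythroid markers (-0.20). Exact ties, at 52.0% of genes for this pair, hold random medians near 0, so medians this small can take extreme percentiles.

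The third comparison sets the labelled array against the control Esam(hi) array. Of 9312 genes above background, 1203 were higher and 110 lower on the labelled array; the lower share of 8.38% became 28.2% with the level trend removed (567 higher, 223 lower) and 22.7% with quantile normalization (719 higher, 211 lower). The genes farthest above were largely those of the first comparison. They were Clec10a (at least 3.47-fold), Clec12a (at least 7.51-fold), Serpinb10 (at least 5.92-fold), Wfdc17 (13.9-fold), Adgre4 (at least 9.73-fold), Clec4a3, Ccr2, Fn1 and Clec4e, with Ly6a2 (11.1-fold), Thbs1 (11.1-fold) and Lyz1 (9.91-fold). With immunoglobulin segments and small RNAs left out, Dtx1 was the gene farthest below, at 8.56 against 11.25 (6.49-fold), followed by Srsy (5.88-fold), Apol7c (5.38-fold), Gpr4 (5.35-fold) and Adgrl3 (5.31-fold). Also lower were Gpm6b (at least 3.80-fold), Stra6l (4.38-fold), Abcb1a (3.99-fold), which encodes a drug efflux pump, Sash1 (3.85-fold), Ifnz and Arap2. Jchain, the joining chain of secreted antibodies, was 4.06-fold lower (8.68 against 10.70).

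Monocyte genes were higher on the labelled array, 21 of 30 at least 2-fold and none lower (median 1.68, percentile 99.99), as were 13 of 20 Fc and C-type lectin receptor genes (median 1.88, percentile 99.99) and 10 of 24 cell cycle genes (median 0.87, percentile 99.99). With the trend removed the lectin receptor count stayed at 13, and 2 cell cycle genes remained 2-fold higher (median 0.61). Neutrophil markers were higher too, 8 of 15 (median 1.00, percentile 99.99), and 4 with the trend removed. Notch targets had a median of -0.53 (percentile 0.09), and the classical DC core list 0.08 against 0.43 for random lists (percentile 0.17), a median that turned negative with the trend removed (-0.30) and with quantile normalization (-0.21). B cell markers had -0.64 (percentile 0.14) from 4 members above background, 3 lower and 1 higher. Erythroid markers had -0.81 (0.39) from 3 members, which is the value of Slc4a1 alone. Slc4a1 read 7.18 on the Esam(hi) array, near background, and 6.37 on the labelled array, below background. Immediate early genes had 0.09 (1.23), which turned negative with the trend removed (-0.23). In all, 5 lists lay below and 10 above the central 95% of random lists.

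Set between the controls, the labelled array lay with the control Esam(lo) array. Over the 1066 genes higher on the control Esam(lo) array its median position was -0.01 (0 is Esam(lo), 1 is Esam(hi)), and 1062 of them lay nearer the Esam(lo) value; over the 75 genes higher on Esam(hi) the median was 0 and all 75 lay nearer Esam(lo). In simulated unchanged arrays, all with noise of the same size, the median was 0.50 in each direction. That was over another selection, the 500 genes farthest apart. Genes were chosen here on the difference between the controls, so a noisier Esam(hi) array alone would also bring the median near 0. The positions and the counts of nearer genes therefore do not separate such noise from a likeness of the Esam(lo) cells. Across 9692 genes above background on at least 1 array, the SD of the difference was 0.15 between the Esam(lo) arrays, 0.57 between the controls and 0.61 between the labelled and the Esam(hi) array. Pearson correlations across genes, which are not independent replicates, were 0.993, 0.900 and 0.887.

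The comparisons against the Esam(hi) array share that array. Of the genes lower on it than on the control Esam(lo) array (1064) and than on the labelled array (1195), 977 were the same genes among 9104 above background in both. Independent lists would share 139.7; simulated unchanged arrays had 0 genes 2-fold apart, so they set no scale for this count. Of those higher on it, 57 of 75 and 110 were shared, against 0.91 for independent lists. The differences correlated across genes at 0.968, against 0.50 in the simulation, with a covariance of 0.33 against 0.01. Because the simulated noise came from the 2 Esam(lo) arrays, a noisier Esam(hi) array alone would raise both values above the simulated ones. Part of this excess may come from the shared array, which cannot be divided, and from its array-wide shift. Against the shared control Esam(lo) array, 1 gene was lower on both others where independent lists would share 2.14, and 0 were higher on both.

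On the measured values, genes at least 2-fold outside both controls were 5 higher on the labelled array (Plcb4, Dcstamp, Bmp2, Itgad and Clec10a) and 12 lower. The lower ones were Adam19, Adgrl3, Apol7c, Asb2, Car1, Dnase1l3, Gpm6b, Hic1, Jchain, Stra6l and the immunoglobulin segments Igkv19-93 and Igkv5-43. With dim values raised to background, a bound added after seeing the data, Bmp2, Itgad and Car1 fall short of 2-fold against at least 1 control. Asb2 and the segments are named here after their values were seen. Adam19 read 9.76 on the control Esam(hi), 9.77 on the control Esam(lo) and 8.54 on the labelled array.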

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

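Of the tests in this part, those of monocyte genes, of other cell types and of both sex-linked explanations were chosen only after the result was seen; the test of a compressed scale was written after the level trend but before the share it measures.

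Outside the named genes, 30 probe sets with no gene name were at least 2-fold higher on the array labelled RBPJ-deficient than on both controls. Their difference from the control Esam(lo) array ran from 1.00 to 2.52 with a median of 1.30. All 30 lie among the 6617 unnamed probe sets whose numbers precede the first named one, and the same block holds 105 probe sets higher on the Esam(hi) array and 6 higher on the control Esam(lo) array. Of the 5529 other unnamed probe sets, 265 were higher on the Esam(hi) array than on both others, 2 on the control Esam(lo) array and 0 on the labelled array. Among 19938 genes these counts were 57, 1 and 5. Only 4.4% of the block of 6617 had an exact tie between arrays, against 57.1% of genes. No gene or explanation is given for the unnamed probe sets.

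Most genes 2-fold apart between the controls were lower on the Esam(hi) array, where all 11 housekeeping genes above background were lower too. A compressed intensity scale of that array could make such a split. With the level trend removed 73.0% were still lower (73.0135%), and the count went from 1141 to 667. This argues against a scale change that follows mean level as the whole cause. An array effect that the trend does not capture stays open, as the housekeeping median was still -0.41 with the trend removed. Less monocyte RNA in Esam(hi) cells stays open: the monocyte list's trend-removed median lay at percentile 0.01 of lists of like level, but its direction had been seen, and the list holds 24 of the 1066 lower genes. Other cell types in the Esam(lo) sort remain open too, although lymphoid and erythroid cells were removed and the gate was CD11c(hi) CD11b+. Of 7 such lists the lowest trend-removed percentiles were 0.03 for neutrophils and 0.12 for red pulp macrophages. B cells (99.83), T cells (92.8), erythroid cells (89.0) and plasmacytoid DCs (88.5) lay on the other side and CD8+ DCs at 20.7. Outside these 7 lists, macrophage core genes lay at 0.02, natural killer markers at 0.6 and platelet markers at 97.1, the last 2 lists with 2 members each. Of 15 neutrophil markers above background, 11 were lower, 3 higher and 1 tied on the Esam(hi) array. S100a8 (8.35 against 10.53), Lcn2, Ltf and Ngp (11.84 against 12.97) were lower and Mpo was higher (9.28 against 8.31). Ngp and Mpo were named after seeing their values. The tables do not separate a different DC state from a different mixture.

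The array labelled RBPJ-deficient and the control Esam(lo) array carried nearly equal values. Median polish over few arrays may draw similar arrays together, and a simulation of 3 arrays with 25 probes and assumed noise gave 26% exact ties. Between the Esam(lo) arrays 52.0% of genes were tied. In the simulation the SD of the difference was 0.10 with median polish and 0.12 with the mean of the probes. Among genes with 3 distinct values the SD of the difference between the Esam(lo) arrays was 0.31 (0.3074) of that between the controls. This lay under the 0.5 set beforehand for median polish. Values that are not tied may be drawn together too, so this result does not decide it. An array-wide shift of the Esam(hi) array that follows mean level would leave similar spreads once the trend is removed. The ratio was 3.52, which argues against such a shift as the only cause. Noise of that single array that does not follow level would remain after this step, so the ratio does not exclude it. No batch is given in the labels, so any day or handling that these arrays shared stays open. So do a likeness of the cells themselves, the median polish and noise of the single Esam(hi) array.

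Xist was higher and Y-linked genes were lower on the array labelled RBPJ-deficient. The tables argue against an array-wide difference: of other genes of like level, none differed from control Esam(lo) as much in the same direction as Xist or Eif2s3y, and 0.40% (0.4016%) as much as Kdm5d, around medians of 0. A larger share of female mice in that pool may account for it, and stays open. With the trend removed all 8 differences of Xist, Eif2s3y, Kdm5d and Uty from the controls had the sign this needs, but 4 of them restate the observation and the rest share the labelled array, so the tally does not decide it. Uty, named after its values were seen, was below background on every array, Kdm5d on the labelled one, and Eif2s3y also differed between the controls (7.47 and 8.36).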

How the results depend on the processing

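The alternatives with protein-coding genes, with 3 distinct values and with dim values raised to background were chosen after seeing the data. No alternative turned the direction of the counts against the Esam(hi) array. The array spreads, not computed for other thresholds or raised dim values, kept their order. The median positions, not computed for raised dim values, stayed from -0.04 to 0.06, near 0 with either sign. The counts that moved by over 1.5 times were as follows. Between the controls, 1141 became 667 with the level trend removed, 608 with the trend removed and protein-coding genes alone, 3349 at 1.5-fold and 208 at 3-fold. Between the labelled and Esam(hi) arrays, 1313 became 790, 714, 3542 and 277 under the same settings. Between the Esam(lo) arrays, 25 became 16 with the stricter filter, 85 at 1.5-fold and 5 at 3-fold, where 3 were higher and 2 lower, so the direction of the split turned; fewer genes reach 3-fold by construction. Medians of called lists that turned were, with quantile normalization, the classical DC core list between the controls (0.1658) and against Esam(hi) (-0.21) and the immediate early list against Esam(hi) (-0.1657); with the trend removed they were 0.2906, -0.3042 and -0.2348. The cause was not tested. Centring each array on its median shifted all genes by -0.12 between the controls and by 0.13 between the labelled and Esam(hi) arrays, and gave 1524 and 1710 genes. Raising dim values to background gave 1014, 21 and 1150 genes in the 3 comparisons; this bound, rather than depth, limits the folds of genes dim on 1 array. A list median was counted as moved when it shifted from its deposited value by at least the SD of the random lists' medians. Of 29 list medians between the controls, 12 stayed, 16 moved and 1 reversed with the trend removed. With quantile normalization 14 stayed, 14 moved and 1 reversed, and all 29 stayed with centring. Between the Esam(lo) arrays, where ties hold the spread of random lists small, 22 of 29 moved with the list mean, 15 with quantile normalization and 9 with centring. No paired analysis was possible because each group has 1 array, and no replicate could be left out.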

Other observations

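Of 19 MHC class II and antigen presentation genes above background, 4 were higher, 13 lower and 2 tied on the control Esam(hi) array against control Esam(lo). Cd86 read 12.18 on the Esam(hi) and 11.35 on the Esam(lo) array, and H2-Eb2 read 12.05 and 11.27. Ctss, a protease that trims the invariant chain, read 10.22 and 11.60, and H2-DMa, which loads peptides, read 10.97 and 12.27. With the trend removed Cd86 (1.19) and H2-Eb2 (1.15) passed 2-fold, and Ctss (-0.98) and H2-DMa (-0.93) fell short of it. The MHC class II genes H2-Aa and H2-Ab1 and the invariant chain gene Cd74 (named after seeing their values) differed by -0.33, -0.25 and -0.07, the first 2 of them within 0.05 of 0 with the trend removed.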
